A study of Homo sapiens with 6 samples.

How the data were processed

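RNA crosslinked to endogenous SSB was measured in 6 HITS-CLIP libraries from MDA-MB-231 cells, 2 each labelled low RNase HMW, low RNase LMW and no RNase. Per the labels' protocols, cells were crosslinked at 400 mJ/cm2 and complexes were recovered with an anti-SSB antibody, and small RNA was treated with polyphosphatase before ligation and amplification. Reads were aligned with BWA 0.7.17-r1188 to hg19, per the submitters' processing notes. The counting tool, strand handling, treatment of reads with several matching loci, removal of PCR duplicates and the tRNA annotation are not given in the sources used here. Such choices decide how reads are split between near-identical tRNA copies, so counts were also summed per isoacceptor, meaning per amino acid and anticodon. A sum does not correct for a read counted at more than 1 copy.

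The authors deposited a table of raw counts per tRNA locus, with 1 column per library and a column of row sums. Where a locus is not listed for a library the table holds the text #N/A, in 19 to 99 of the 540 rows per library, and these cells were read as 0. All remaining cells were checked to be whole numbers, and the deposited sum equalled the sum of the 6 libraries in every row, with 0 exceptions. A further deposited sheet without library names in its header was not used here. The loci carry hg19 names with chromosome, locus number, amino acid and anticodon; 481 have an amino acid name, 58 are named pseudo or undetermined and 1 is a suppressor. Start, end, strand and introns of each locus were not looked up, since no hg19 tRNA annotation was used here. Other RNA polymerase III transcripts and mitochondrial tRNAs were not analysed here. Library totals ranged from 5500 to 39060 counts. A count of 0 was taken to allow up to 3 counts.

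Libraries were grouped by their titles. Shares are percentages of all tRNA counts in a library, averaged over the 2 libraries of a group. Loci and isoacceptors were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test on all 6 libraries with group as the only term, which leaves 3 residual degrees of freedom, after filterByExpr by group and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 389 loci and 52 isoacceptors. Standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic. Values in CPM were computed from the TMM-scaled library sizes. TMM factors were computed separately for loci and for isoacceptors. At the locus level they were lower for HMW (1.0129 and 0.8625 against 1.0573 and 0.9851) and higher for LMW (1.0966 and 1.1344 against 0.9268 and 1.108). Log2 fold changes of LMW over HMW are therefore shifted down for loci relative to sums, and the 2 levels are not on one scale. The biological coefficient of variation was 0.214 for loci and 0.185 for isoacceptors. Sets of loci were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01, two-sided, over 24 sets with at least 3 tested loci: the amino acid families and the lists of intron-containing isoacceptors, long variable arm families, families of YBX1-bound fragments and pseudo or undetermined loci. Library pairs were compared by a chi-square test of their counts and by the edgeR common dispersion of the pair, given as its square root. Exact permutation tests and permutations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

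The same steps were tested on simulated counts with the real means and library sizes. Loci were drawn independently, with the fitted common dispersion, or with a fixed value close to it for the set test. Of loci changed 2-fold, 52.1% were recovered for LMW against HMW, 40% for LMW against no RNase and 32.4% for HMW against no RNase; of loci changed 4-fold, 97.4%, 92.5% and 91.1% were recovered. Of unchanged loci 1.24%, 1.69% and 1.25% were called. All libraries were simulated with the same spread. In the data, the square root of the pair dispersion was 0.0307 for HMW replicate 1 with no RNase replicate 1. It was 0.299 to 0.520 for pairs with HMW replicate 2. The simulated rates therefore do not cover data in which 1 library lies that far from the rest. A set shifted 2-fold was called in each comparison, with 0 unrelated sets called. Because the simulated loci were independent, this could not show whether correlated loci give false set calls under the preset correlation.

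Groups, tests, lists, the rule for named loci and the alternatives were fixed before the data were examined, except for the alternatives named in the closing section as chosen afterwards. Named loci were up to 10 in each direction with the largest log2 fold change among those past the threshold whose groups did not overlap, or the 5 with the smallest p where fewer than 5 passed; the 10 loci with the largest mean share in each group; all isoacceptors past the threshold; and always tyrosine, methionine and selenocysteine tRNAs and the most abundant members of each list. Alternatives were DESeq2 1.42.0 size factors, library totals only, no count filter, a filter of 10 counts in 4 libraries, the replicate number as a block, only the 2 groups compared, the DESeq2 Wald test, each library left out in turn, camera with an estimated correlation and fry. Merging loci of one isoacceptor with identical counts merged 0 loci.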

Results

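SSB, the La protein, is an RNA-binding protein that binds the uridine-rich 3' ends of RNA polymerase III transcripts, among them precursor tRNAs. Its endogenous RNA contacts were recorded by HITS-CLIP, in which RNA is crosslinked to protein by ultraviolet light, recovered by immunoprecipitation and sequenced, in MDA-MB-231 cells, a human triple-negative breast cancer line, after crosslinking at 400 mJ/cm2. The 6 libraries fell into 3 groups of 2. Lysates received low RNase or no RNase, and the low RNase libraries were labelled HMW or LMW, abbreviations that the labels do not spell out. Whether HMW and LMW libraries with the same replicate number came from 1 immunoprecipitate is not stated, and the groups were tested as unpaired. The deposited table lists raw counts at 540 tRNA loci, named in the hg19 genome by chromosome, locus number, amino acid and anticodon. Counts per locus do not tell reads from precursor tRNAs, mature tRNAs and tRNA fragments apart. Library totals were 29383 and 19115 counts for HMW, 27524 and 39060 for LMW, and 18151 and 5500 for no RNase, so that 1 count stood for 0.00256% to 0.0182% of a library and a count of 0 allowed a share of up to 0.0077% to 0.0545%. These limits cover counting error only, because molecular identifiers are not mentioned in the labels. No input or control immunoprecipitation library was analysed here, so cellular abundance is not separated from binding. The labels do not say that replicates came from separate cultures, and p-values then measure only the spread between these samples, which may be technical.

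The first question was which tRNAs were recovered with SSB. Glycine tRNAs made up the largest family in every group, with 28.0% ± 0.88 of all counts in HMW, 25.3% ± 3.22 in LMW and 32.9% ± 7.63 without RNase (SD, n = 2 for each share here). Most of this came from tRNA-Gly with anticodon TCC, at 25.7% ± 0.83, 22.8% ± 3.27 and 29.4% ± 5.98 of counts, from 9 of the 540 loci. Counts at 4 of these loci on chromosome 1 differed by less than the sampling noise (chi-square 1.87 on 18 degrees of freedom). So low a value argues against separate counts at these 4 loci, which were picked because their counts matched. If reads were counted at each matching copy, which the sources used here do not state, the Gly-TCC and glycine shares would be inflated. Leucine tRNAs were next in each group at 10.8% ± 1.24, 8.63% ± 0.89 and 9.39% ± 0.02, and arginine tRNAs held 7.76% ± 0.01, 6.47% ± 1.21 and 6.97% ± 1.24. In LMW, methionine, tyrosine and cysteine tRNAs lay above arginine tRNAs. Tyrosine tRNAs held 6.12% ± 0.88, 7.34% ± 0.48 and 6.59% ± 0.58, and methionine tRNAs 5.83% ± 1.02, 7.55% ± 0.21 and 5.73% ± 0.91. Initiator and elongator methionine tRNAs share the CAT anticodon and are not told apart by the locus names. Cysteine tRNAs were at 3.43% ± 1.76 in HMW, 7.22% ± 0.69 in LMW and 4.59% ± 0.84 without RNase. Selenocysteine tRNA, from 2 loci, was at 0.125% ± 0.0083, 0.0589% ± 0.0217 and 0.104% ± 0.007. A permutation test of 2 libraries against 2 cannot give an exact p below 0.333, so the shares were not tested by permutation, and the sums of counts per isoacceptor were tested between groups with edgeR instead.

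**Figure D1:**
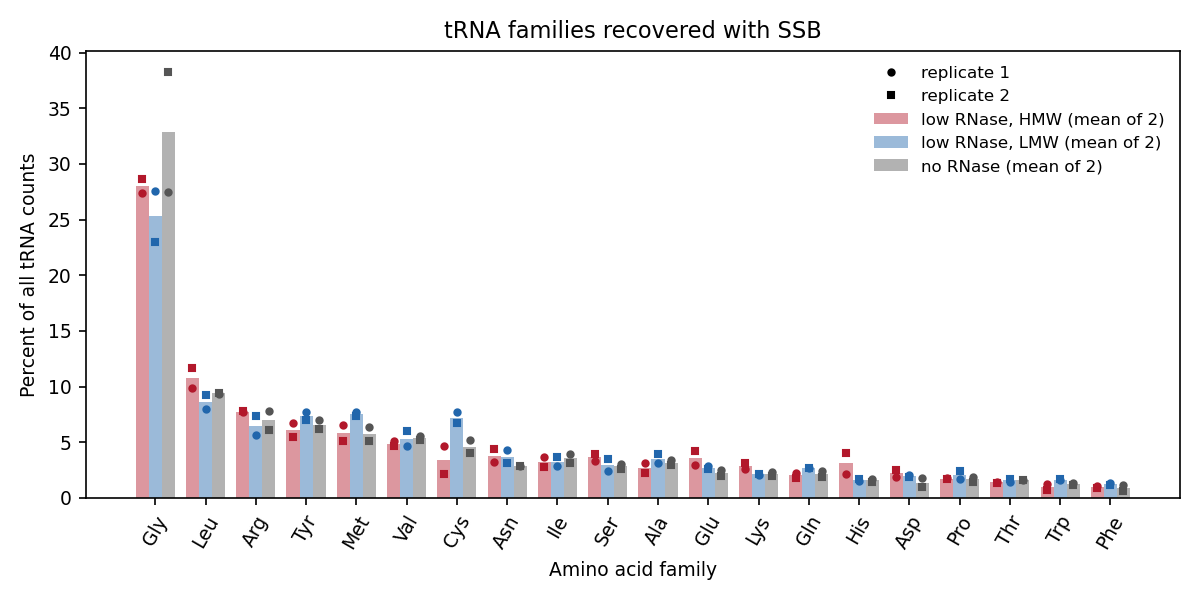
Percent of all tRNA counts (vertical axis) per amino acid family (horizontal axis) in the 3 groups, with bars for the mean of 2 libraries and points for each library. Glycine stands at 25.3% to 32.9% on average, and cysteine is at 7.22% in LMW against 3.43% in HMW.

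The 10 most abundant loci were shared by all 3 groups, and 8 of them were tRNA-Gly-TCC loci. Together they held 29.7% ± 1.44 of counts in HMW, 25.3% ± 2.91 in LMW and 33.2% ± 5.92 without RNase (SD, n = 2). The leading locus, chr1.tRNA45-GlyTCC on chromosome 1, took 3.91% ± 0.28, 3.19% ± 0.33 and 4.30% ± 0.68. It was followed by chr1.tRNA117-GlyTCC at 3.82% ± 0.35, 3.0% ± 0.29 and 4.11% ± 0.74. The chromosome 1 loci chr1.tRNA70-GlyTCC, chr1.tRNA73-GlyTCC, chr1.tRNA76-GlyTCC and chr1.tRNA79-GlyTCC each averaged 2.67% to 3.60%, and chr19.tRNA2-GlyTCC and chr17.tRNA10-GlyTCC, on chromosomes 19 and 17, averaged 2.24% to 3.13%. The remaining pair was chr6.tRNA100-LeuCAA on chromosome 6, at 2.79% ± 0.54, 1.78% ± 0.23 and 3.0% ± 0.50, and chr8.tRNA4-TyrGTA on chromosome 8, at 1.51% ± 0.02, 1.12% ± 0.12 and 1.42% ± 0.28. Start and end positions of the loci were not looked up, and reads that fit several near-identical copies make every value for a single locus uncertain.

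Among the lists fixed before the data were examined, the isoacceptors whose human genes carry introns (Tyr-GTA, Arg-TCT, Leu-CAA and Ile-TAT) covered 32 loci, 5.93% of those listed, and took 15.6% ± 0.79 of counts in HMW, 14.9% ± 1.15 in LMW and 16.7% ± 0.85 without RNase (SD, n = 2). Their most abundant members after chr6.tRNA100-LeuCAA and chr8.tRNA4-TyrGTA were chr19.tRNA10-IleTAT at 1.16% ± 0.13, 0.972% ± 0.219 and 1.33% ± 0.11, and chr17.tRNA4-ArgTCT at 1.18% ± 0.03, 0.822% ± 0.217 and 1.20% ± 0.20. The families with a long variable arm (Leu, Ser and selenocysteine, 66 loci) took 14.6% ± 1.69, 11.6% ± 1.68 and 12.3% ± 0.29. The families whose fragments are known ligands of the RNA-binding protein YBX1 (Glu, Asp, Gly and Tyr, 85 loci) took 39.9% ± 1.33, 37.3% ± 4.01 and 43.0% ± 6.11. Loci named as pseudo or undetermined, 58 of the 540, took 0.748% ± 0.184, 1.05% ± 0.01 and 1.0% ± 0.08.

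The second question was whether the LMW and HMW libraries, both from low RNase lysates, held different tRNAs. Of 389 loci tested, 16 were higher and 31 lower in LMW. With libraries scaled by their totals only, which moved the median locus by 0.24 towards LMW, the balance turned to 30 higher and 12 lower. The higher loci were led by tRNA-Cys-GCA, with 9 of the 16, and included 4 tRNA-Tyr-GTA loci. The lower loci were spread over 17 isoacceptors and were led by tRNA-His-GTG with 6, followed by tRNA-Leu-AAG, tRNA-Lys-TTT and tRNA-Val-TAC with 3 each. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Over all tested loci, 219 of 389 (56.3%) had both LMW libraries on one side of both HMW libraries, where chance alone gives 33.3% on average. Loci of 1 isoacceptor varied together, so this share can lie far from 33.3% without a group difference and does not test for one. The share in the comparisons with no RNase, where no locus was called, was 188 of 389 loci (48.3%) for LMW and 175 of 389 for HMW. DESeq2 called 9 of the 110 loci to which it gave an adjusted p, all lower in LMW and all among the 47. The call count rested on single libraries, being 126 without HMW replicate 1, 1 without HMW replicate 2, 0 without either LMW replicate, and 28 without either no RNase replicate.

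Among isoacceptors with an amino acid name, Cys-GCA had the largest log2 fold change in LMW relative to HMW. It rose by a log2 fold change of 1.11 (SE 0.31, edgeR adjusted p = 0.0331), from 33287 ± 15695 CPM (TMM-scaled read counts) in HMW to 72229 ± 15888 in LMW (SD, n = 2 libraries), and both LMW libraries lay above both HMW libraries. All 29 tested cysteine loci had positive log2 fold changes, 9 past the threshold over all loci tested and 19 when adjusted over the list alone, with a median of 1.03. The largest changes were on chromosome 7. The locus chr7.tRNA8-CysGCA rose by 2.07 (SE 0.45), from 279.5 ± 135.5 to 1291 ± 133 CPM, and chr7.tRNA13-CysGCA, chr7.tRNA22-CysGCA, chr7.tRNA10-CysGCA, chr7.tRNA11-CysGCA and chr7.tRNA23-CysGCA rose by 1.41 to 1.61. On chromosome 3, chr3.tRNA6-CysGCA rose by 1.51 (SE 0.39). Loci without a cysteine name among the 10 largest increases were chr1.tRNA136-AsnGTT at 1.59 (SE 0.43), chr2.tRNA25-PseudoCTC at 1.44 (SE 0.50) and chr8.tRNA12-TyrGTA at 1.39 (SE 0.40). The Pseudo-CTC loci also passed as a sum, at 1.80 (SE 0.49, edgeR adjusted p = 0.0331). As a set the cysteine loci stood above the other loci (camera adjusted p = 1.63e-14), a call that was lost with an estimated correlation between loci (adjusted p = 0.632). The sums of the cysteine and Pseudo-CTC loci missed the threshold with a filter of 10 counts in 4 libraries, without HMW replicate 2 and without either LMW replicate, and the Pseudo-CTC sum also with DESeq2. All 29 cysteine loci had positive values in each fit that left out 1 library, with a median of 1.92 without HMW replicate 1, and the cysteine sum was at 1.70 without HMW replicate 1 and 0.63 without HMW replicate 2. Near-identical copies may share reads, so the agreement of these 29 loci does not stand for 29 separate observations. The 5 chromosome 7 loci named as a group had 2.55 to 3.27 without HMW replicate 1, and chr7.tRNA11-CysGCA had 0.99 without HMW replicate 2. The locus chr8.tRNA12-TyrGTA had 2.96 without HMW replicate 1 and 0.83 without HMW replicate 2, and chr2.tRNA25-PseudoCTC had 2.39 without HMW replicate 1. Without LMW replicate 1, chr1.tRNA136-AsnGTT had 0.93, chr2.tRNA25-PseudoCTC 0.79 and the Pseudo-CTC sum 0.97.

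Histidine tRNA moved the other way. His-GTG fell by 0.92 on the log2 scale (SE 0.28, edgeR adjusted p = 0.0475), from 30763 ± 14815 CPM in HMW to 16174 ± 956 in LMW (SD, n = 2). All 9 tested histidine loci had negative values, 6 of them past the threshold and 9 when adjusted over the list alone. The locus chr6.tRNA33-HisGTG on chromosome 6 fell by 1.49 (SE 0.39) and chr15.tRNA8-HisGTG on chromosome 15 by 1.46 (SE 0.34). The set lay below the other loci (camera adjusted p = 0.000372, but adjusted p = 0.632 with an estimated correlation). Without HMW replicate 2 the median of the 9 loci was -0.45 in place of -1.08, chr6.tRNA33-HisGTG had -0.70, chr15.tRNA8-HisGTG -0.80 and the sum -0.40, and no histidine locus passed there or without either LMW replicate. The sum of the histidine loci missed the threshold in those fits too, and with DESeq2, with library totals only, with a filter of 10 counts in 4 libraries, and with the 4 libraries of these groups alone.

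Among the remaining loci with the largest decreases, chr17.tRNA14-ThrCGT on chromosome 17 fell by 2.91 (SE 0.57), from 1457 ± 1144 to 155.0 ± 171.4 CPM (SD, n = 2). Its LMW value rests on few counts. The lysine locus chr19.tRNA5-LysCTT fell by 2.25 (SE 0.72), a call that ended with library totals only, with the 4 libraries of these groups alone and without any single library other than HMW replicate 1. The glutamate loci chr13.tRNA5-GluTTC and chr2.tRNA20-GluTTC fell by 1.74 (SE 0.44) and 1.71 (SE 0.39). The serine locus chr6.tRNA145-SerAGA fell by 1.62 (SE 0.37), chr1.tRNA124-AsnGTT by 1.49 (SE 0.41) and chr6.tRNA131-GlnCTG by 1.38 (SE 0.37). Selenocysteine tRNA, which decodes UGA at selenoprotein codons, fell by 1.55 at its tested locus chr19.tRNA8-SeCTCA (SE 0.43), from 1172 ± 161 to 371.4 ± 190.8, while the sum of its loci had a log2 fold change of -1.04 (SE 0.46, edgeR adjusted p = 0.157). Sums were scaled apart from loci, so part of this gap reflects the scaling. Of the asparagine loci named here, one was higher and one lower. Single libraries moved some of these values, chr17.tRNA14-ThrCGT to -1.85 without HMW replicate 2 and -5.10 without LMW replicate 2, and chr6.tRNA131-GlnCTG to -0.74 without HMW replicate 2.

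Tyrosine tRNA as a whole did not pass the test between LMW and HMW, with a log2 fold change of 0.29 (SE 0.28, edgeR adjusted p = 0.452) for the sum of its loci. Its 13 tested loci, which were scaled apart from the sum, went both ways, with 8 positive and 5 negative values and 0 called lower. The 4 past the threshold, higher by 1.11 to 1.39, were chr8.tRNA12-TyrGTA, chr14.tRNA18-TyrGTA, chr14.tRNA19-TyrGTA and chr6.tRNA15-TyrGTA, the last 3 named after their values were seen. These 4 averaged 668.4 to 1684 CPM in HMW. When adjusted over the list alone, 6 tyrosine loci passed. Without HMW replicate 1, chr8.tRNA12-TyrGTA had 2.96 and chr6.tRNA15-TyrGTA 1.94, and without HMW replicate 2 these 2 loci had 0.83 and 0.66. The most abundant locus, chr8.tRNA4-TyrGTA at 16401 CPM in HMW, had a log2 fold change of -0.68 (SE 0.29, edgeR adjusted p = 0.116). The methionine sum had 0.40 (SE 0.28, edgeR adjusted p = 0.331).

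Of the 4 fixed lists, the long variable arm list was the only one past the set threshold between LMW and HMW, with 8 of 55 tested loci lower, none higher and 47 not past the test (camera adjusted p = 0.007, but adjusted p = 0.632 with an estimated correlation). Its median log2 fold change was -0.23, and 0.0039 when libraries were scaled by their totals only, -0.39 without HMW replicate 1 and -0.49 without LMW replicate 2. Its abundant members chr6.tRNA74-LeuCAA, chr1.tRNA58-LeuCAA and chr16.tRNA27-LeuTAG had -0.36, -0.23 and -0.58 without passing, whereas chr6.tRNA100-LeuCAA fell by 0.91 (SE 0.29, edgeR adjusted p = 0.0358) and had -0.57 without HMW replicate 2. The intron-containing isoacceptors had 4 loci higher, 2 lower and 22 not past the test, with 6 adjusted over the list alone (camera adjusted p = 0.878), and their median of -0.09 and mean of 0.04 differed in sign, the median being 0.15 with library totals only and 0.18 without HMW replicate 1. The YBX1-related families had 4 loci higher, 2 lower and 64 not past the test, with 4 adjusted over the list alone (camera adjusted p = 0.084). This list passed as lower without HMW replicate 1 (camera adjusted p = 0.0491, 9 loci higher and 16 lower) and without LMW replicate 1 (camera adjusted p = 0.0052). Their abundant members chr1.tRNA45-GlyTCC and chr1.tRNA117-GlyTCC had -0.55 and -0.60 without passing. The pseudo or undetermined loci had 1 of 7 higher, and 1 adjusted over the list alone (camera adjusted p = 0.475), and their abundant members chr6.tRNA41-PseudoACT and chr18.tRNA3-PseudoTCC had -0.38 and -0.29. Among amino acid families, Cys, Gln, Ala and Trp passed as higher and His, Glu, Lys, Arg and Leu as lower under the preset correlation, and none passed with an estimated correlation (smallest adjusted p = 0.632) or with fry (smallest adjusted p = 0.327). The Ala, Gln, Leu and Trp calls ended without HMW replicate 2, the Ala and Trp calls without LMW replicate 2, the Trp call without no RNase replicate 1, and the Arg call without HMW replicate 1 or LMW replicate 1. The Gln and Leu calls also ended with a filter of 10 counts in 4 libraries, and the Ala and Trp calls with no filter. With libraries scaled by their totals only, 71.4% of the called loci were higher, where TMM scaling gave 34.0%, and the cysteine median was 1.27 and the histidine median -0.81.

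**Figure D2:**
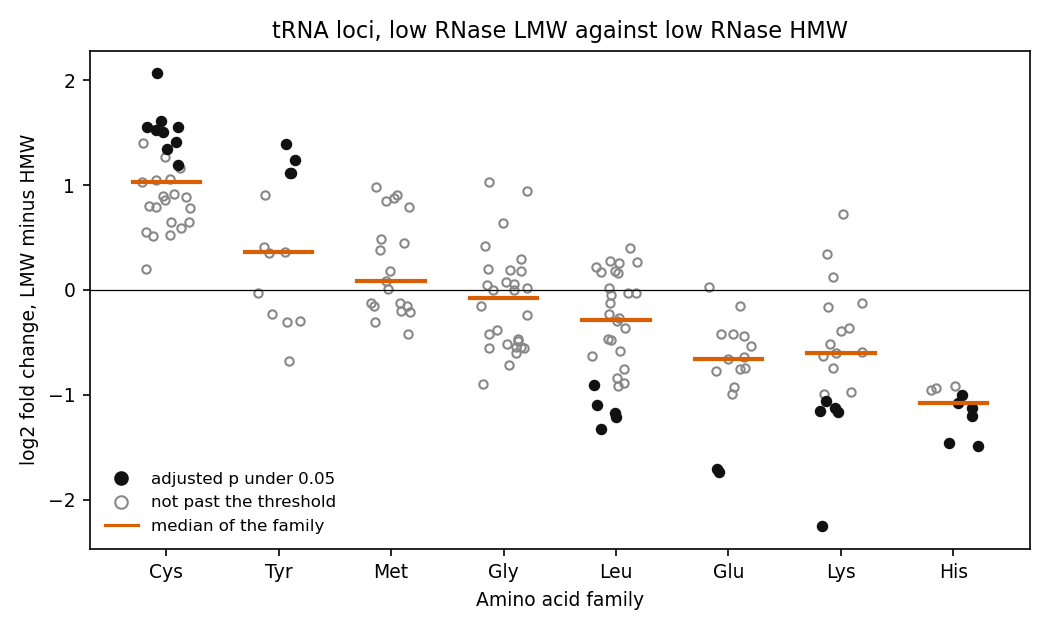
Log2 fold change of LMW over HMW (vertical axis) for each tested locus of 8 amino acid families (horizontal axis), with filled points for loci past an adjusted p of 0.05, open points for the rest and a bar for the family median, in counts scaled by TMM. All 29 cysteine loci lie above 0 and all 9 histidine loci below, whereas scaling by library totals only would raise the median locus by 0.24.

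The third question was how the LMW libraries compared with libraries made without RNase. No locus passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 28 of 389 at an unadjusted p under 0.05 and 0 called by DESeq2. No isoacceptor passed either, with 4 of 52 at an unadjusted p under 0.05 and 0 called by DESeq2. The 5 loci with the smallest p were chr6.tRNA100-LeuCAA at a log2 fold change of -0.96 (SE 0.30), chr1.tRNA9-ArgTCT at -0.94 (SE 0.32), chr1.tRNA131-GlyCCC at -1.14 (SE 0.40), chr7.tRNA10-CysGCA at 1.17 (SE 0.46) and chr17.tRNA4-ArgTCT at -0.76 (SE 0.31), each with an edgeR adjusted p of 0.653. Without no RNase replicate 1, chr7.tRNA10-CysGCA had 0.65. All 29 cysteine loci had positive values, with a median of 0.60, and the set stood above the other loci (camera adjusted p = 1.81e-07, but adjusted p = 0.874 with an estimated correlation). The glycine loci, 24 of 28 negative with a median of -0.59, stood below (camera adjusted p = 2.9e-06, but adjusted p = 0.874 with an estimated correlation). The glycine call ended without no RNase replicate 2, the shallowest library (camera adjusted p = 0.919, median -0.10), and the glycine median was -0.95 without no RNase replicate 1. The 4 fixed lists did not pass, with 0 loci called in any of them, also when adjusted over each list alone, and adjusted p from camera of 0.161 for the intron-containing isoacceptors, 0.215 for the long variable arm, 0.213 for the YBX1-related families and 0.859 for the pseudo or undetermined loci, whose median of -0.25 and mean of 0.07 differ in sign. Without LMW replicate 1 the YBX1-related families passed (camera adjusted p = 0.0028). Scaling by library totals only moved the median locus of this comparison by 0.19. The sums of Tyr-GTA, Met-CAT and SeC-TCA had log2 fold changes of 0.10 (SE 0.28), 0.34 (SE 0.28) and -0.80 (SE 0.55).

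The fourth question was how the HMW libraries compared with libraries made without RNase. Again no locus passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 39 of 389 at an unadjusted p under 0.05 and 0 called by DESeq2, and no isoacceptor passed, with 7 of 52 at an unadjusted p under 0.05 and 0 called by DESeq2. The 5 loci with the smallest p were chr1.tRNA111-HisGTG at a log2 fold change of 1.57 (SE 0.47), chr16.tRNA18-GlyGCC at -1.65 (SE 0.50), chr14.tRNA1-LeuAAG at 1.32 (SE 0.40), chr1.tRNA67-LeuCAG at 1.30 (SE 0.40) and chr9.tRNA7-HisGTG at 1.42 (SE 0.47), with edgeR adjusted p of 0.196 to 0.249. All 5 passed without HMW replicate 1, and chr16.tRNA18-GlyGCC also without no RNase replicate 1 (edgeR adjusted p = 0.0033). Its value was -3.06 and -2.69 in those fits, -1.08 without HMW replicate 2 and -0.89 without no RNase replicate 2. Without HMW replicate 2, chr14.tRNA1-LeuAAG had 0.86, chr1.tRNA67-LeuCAG 0.58 and chr9.tRNA7-HisGTG 0.77. All 9 histidine loci had positive values with a median of 1.08, 6 of them past the threshold when adjusted over the list alone, and the set stood above the other loci (camera adjusted p = 8.42e-05, but adjusted p = 0.636 with an estimated correlation). Glutamate, aspartate and lysine loci also stood above the rest, with medians of 0.84, 0.62 and 0.47, and cysteine, glycine and alanine loci below, with medians of -0.44, -0.27 and -0.27, and none of these 6 passed with an estimated correlation (adjusted p = 0.636). Single libraries moved these medians. Without HMW replicate 2 they were 0.31 for histidine, 0.40 for glutamate, 0.30 for aspartate, 0.14 for lysine, -0.16 for cysteine and -0.05 for alanine. Without HMW replicate 1 they were 1.71 for histidine, 0.98 for aspartate, -1.25 for cysteine, -0.69 for alanine and -0.15 for glycine, and without no RNase replicate 1 they were 1.28 for aspartate and -0.82 for glycine. The 4 fixed lists did not pass, with 0 loci called in any of them, also when adjusted over each list alone, and adjusted p from camera of 0.0679 for the intron-containing isoacceptors, 0.0678 for the long variable arm, 0.569 for the YBX1-related families and 0.206 for the pseudo or undetermined loci. The YBX1-related families had a median of -0.04 and a mean of 0.11, which differ in sign. Without no RNase replicate 2 they passed as higher (camera adjusted p = 0.0282, median 0.22), whereas their median was -0.41 without no RNase replicate 1, and 14 of their loci were higher and 5 lower without HMW replicate 1. The long variable arm list passed as higher without no RNase replicate 2 (camera adjusted p = 0.0282) and with a filter of 10 counts in 4 libraries (camera adjusted p = 0.0267), and had 11 loci higher without HMW replicate 1. The intron-containing isoacceptors passed as lower with that filter (camera adjusted p = 0.0357), and had 2 loci lower without HMW replicate 1. The sums of Tyr-GTA, Met-CAT and SeC-TCA had log2 fold changes of -0.19 (SE 0.28), -0.05 (SE 0.28) and 0.24 (SE 0.53), the methionine value turning positive under several other settings. Without HMW replicate 1, 69 loci and 11 isoacceptors passed, and without no RNase replicate 1, 1 locus and 1 isoacceptor passed. Without HMW replicate 2 the cysteine and alanine set calls ended (camera adjusted p = 0.278 for both), the alanine call also ended without no RNase replicate 1, and the glycine call ended without HMW replicate 1 and without no RNase replicate 2, where the glycine median was 0.15.

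Distances between libraries did not follow the groups throughout. Over the 389 tested loci, HMW replicate 1 and no RNase replicate 1 differed by less than the sampling noise, with a chi-square of 0.93 per degree of freedom (p = 0.835) and a coefficient of variation beyond counting noise of 0.0307. Replicates of one group differed by more, at 0.142 for no RNase, 0.160 for LMW and 0.299 for HMW. HMW replicate 2 was the library farthest from the others, at 0.299 to 0.520. With HMW replicate 1 and no RNase replicate 1 both left out, a setting chosen after the data were examined, 95 loci passed between LMW and HMW, 46 of them among the 47, and 0 and 1 passed for LMW and HMW against no RNase. HMW and no RNase then held 1 library each, so the spread in that fit came from the 2 LMW libraries only.

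**Figure D3:**
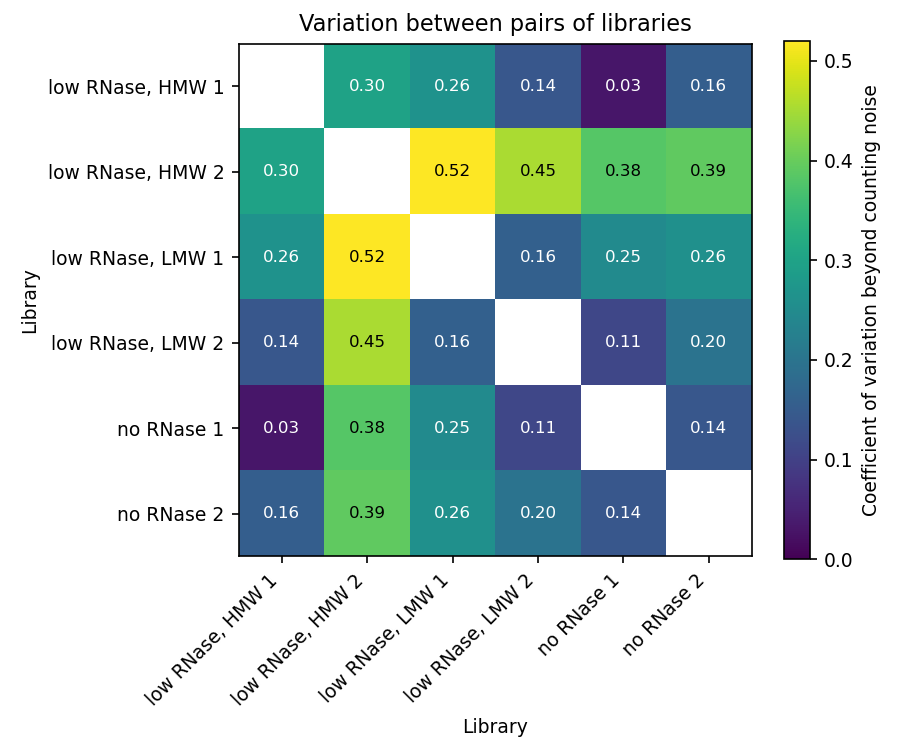
Coefficient of variation beyond counting noise (colour and printed values) for each pair of the 6 libraries over the 389 tested loci, with libraries on both axes by group and replicate number. The pair of HMW replicate 1 and no RNase replicate 1 is lowest at 0.0307, and the pairs with HMW replicate 2 range from 0.299 to 0.520.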

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

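Thinning, and leaving out HMW replicate 1 and no RNase replicate 1 together, were chosen only after the data were examined; all other settings were fixed beforehand. For LMW against HMW, where 47 loci passed, 29 passed with DESeq2 size factors (29 of them among the 47), 27 with only the 2 groups compared, 9 with the DESeq2 Wald test, and medians of 18 (range 4 to 32) and 27 (range 0 to 39) over 20 draws when the HMW or the LMW libraries were thinned to the no RNase totals, so that depth limits this count. The 3 isoacceptors became 0 with a filter of 10 counts in 4 libraries and 1 with the DESeq2 Wald test. With HMW replicate 1 and no RNase replicate 1 both left out, 95 loci and 8 isoacceptors passed for LMW against HMW, 1 isoacceptor and 4 sets for LMW against no RNase, and 1 locus and 5 isoacceptors for HMW against no RNase, with HMW and no RNase at 1 library each and the spread taken from the 2 LMW libraries only. With no filter, 2 isoacceptors passed for HMW against no RNase. With an estimated correlation, and with fry, 0 sets passed in each of the 3 comparisons, against 10, 2 and 7. Leaving out 1 library at a time gave 0 to 126 loci, 0 to 16 isoacceptors and 6 to 12 sets for LMW against HMW, 0 loci, 0 isoacceptors and 1 to 4 sets for LMW against no RNase, and 0 to 69 loci, 0 to 11 isoacceptors and 5 to 11 sets for HMW against no RNase. In such fits a group left with 1 library is assumed to vary like the other groups. The glycine share in HMW was 25.1% with the most abundant locus left out of the total, and 27.4% to 28.7% with 1 library. The Met-CAT value for HMW against no RNase, -0.05, ranged from -0.19 to 0.13 with 1 library left out and reversed to 0.0101 with DESeq2 size factors, 0.0201 with library totals only, 0.0373 with no filter, 0.0149 with only the 2 groups, 0.0099 with the DESeq2 Wald test, and 0.13 without HMW replicate 2, 0.007 without LMW replicate 2 and 0.0159 without no RNase replicate 1. The Tyr-GTA value for LMW against no RNase, 0.10, reversed to -0.10 without LMW replicate 1 and was 0.30 without LMW replicate 2; none of these values passed the test. Of the remaining values for named loci and isoacceptors, 180 kept their direction and side of the threshold with 1 library left out and 86 lost and 6 gained a call, against 318, 23 and 2 under other settings. With the replicate number as a block, 47 loci passed for LMW against HMW, 43 of them among the 47 of the unblocked fit, with 4 isoacceptors and 9 sets; the His-GTG call ended (edgeR adjusted p = 0.176), the Trp set call ended and the SeC-TCA sum passed. Against no RNase the block gave 0 loci, 0 isoacceptors and 2 sets for LMW and 0, 0 and 7 for HMW. Deviations of libraries with the same number correlated across loci at 0.105, -0.04 and -0.03, so the numbers are not shown to pair the samples. Merging loci with identical counts merged 0 loci and tested nothing. The causes of these changes were not tested, apart from the depth set by thinning.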

Other observations

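Tests below were chosen after the result was seen, except the permutation over isoacceptors for HMW replicate 2. Cysteine tRNA loci cluster on chromosome 7, where 17 tested loci had a median log2 fold change of 1.19 for LMW over HMW and 8 were called. On chromosome 17, 6 cysteine loci had a median of 0.55 and 0 were called, and the difference between these chromosomes was not tested. The chromosome 1 tRNA-Gly-TCC loci tRNA70, tRNA73, tRNA76 and tRNA79 had totals of 4091 to 4129 over the 6 libraries and differed by less than the sampling noise (chi-square 1.87 on 18 degrees of freedom), and were picked for that test because their counts matched. Separate counts of equal mean would give a chi-square near its 18 degrees of freedom, so 1.87 argues against separate counts at these 4 loci. Picking them lowers the value by an amount that was not tested, and how many reads they share is not known. For tRNA45 and tRNA117 of chromosome 1 (5.84 on 6) and the loci of chromosomes 19 and 17 (2.37 on 6) the chi-square was within what separate counts of equal mean give, whereas the counts of all 8 of these loci together differed by more than that (566.2 on 42, p = 5.36e-93).

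HMW replicate 1 and no RNase replicate 1 carry different RNase labels but matching tRNA profiles. Over the 389 tested loci their counts gave a chi-square p of 0.835, whereas each of the other 14 pairs differed, and the 5 pairs compared at matched or lower depth kept chi-square values of 1.41 to 4.21 per degree of freedom. That libraries labelled HMW keep the untreated profile in both replicate numbers is argued against by HMW replicate 2 and no RNase replicate 2, with 3.42 per degree of freedom. Shared material or a label mix-up may account for the match, a possibility the counts allow but cannot establish. An untreated-like profile in the first HMW replicate alone also stays open, and the counts of loci called against no RNase rest on both libraries.

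HMW replicate 2 stands apart from the other libraries, and 46 of the 47 calls between LMW and HMW were lost without it, as all 47 were without either LMW replicate, but of these 3 fits it was the one that moved both the Cys-GCA sum (1.11 to 0.63) and the His-GTG sum (-0.92 to -0.40) by over 1.5 times, with 0.87 and -0.98 without LMW replicate 1 and 1.26 and -0.89 without LMW replicate 2. Noise that is independent from locus to locus is argued against, since 49.3% of the variance of its deviation lay between isoacceptors, where permuted labels gave 26.8% at most (p = 1e-05, the smallest that 100000 permutations can give). All 9 tested His-GTG loci deviated by 1.17 to 1.75 and all 29 Cys-GCA loci by -2.17 to -0.16 on the log2 scale. These families were picked from a comparison that this library moves, so their deviations add no separate support. Noise shared by near-identical copies of an isoacceptor stays open. The share was 50.3% and 54.0% in the LMW libraries, 28.6% in HMW replicate 1, and 34.15% and 35.1% in the no RNase libraries, so such sharing was not particular to HMW replicate 2. Fewer reads are argued against as the whole cause, since its closest library was at a coefficient of variation of 0.299, whereas no RNase replicate 1, with fewer counts, was within 0.111 of LMW replicate 2. A difference in how that library was prepared and a true property of the material labelled HMW both stay open and untested.

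The intron-containing isoacceptors Leu-CAA, Tyr-GTA, Ile-TAT and Arg-TCT ranked 2 to 5 of 49 isoacceptors by mean share of counts per locus, after Gly-TCC. Their share per locus was 4.45 times that of the others as a ratio of geometric means (exact permutation over 211876 choices of 4 isoacceptors, two-sided p = 0.00292), with p of 0.00135 to 0.009 in the single libraries. A smaller number of listed loci does not account for it as the whole cause, since the difference was 3.59 times among the 30 isoacceptors with 5 to 14 loci (two-sided exact permutation p = 0.0081). Reads concentrated on 1 or 2 loci of each family stay open, since the most abundant locus held 58.8% of the Leu-CAA, 51.4% of the Ile-TAT, 42.3% of the Arg-TCT and 20.2% of the Tyr-GTA share, and among those 30 isoacceptors the difference was 2.75 times without the most abundant locus of each (p = 0.0381) and 2.34 times for the median locus (p = 0.0907, both two-sided exact permutation). No biological explanation was tested, and higher cellular abundance of these tRNAs and the longer target that an intron gives to reads stay open, because no input library and no locus lengths were used here.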
